A study of Mus musculus with 24 samples.

How the data were processed

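Bulk RNA sequencing was done on 24 libraries of mouse muscle stem cells, in 6 groups of 4 libraries formed by 2 genotypes (WT and KO) and 3 days of injury (0, 1 and 4). All libraries carry batch label 1, and the labels give replicate numbers without saying whether a number marks an animal. Libraries were made with the SMART-Seq v4 kit, per the labels' protocols. Reads were checked with FastQC, aligned with STAR and counted with RSEM, and values were normalised with limma, with mm39 as the genome build, per the submitters' processing notes, which give no versions and do not state whether strand was used.

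The deposited table holds a linear normalised signal for 17111 genes. Each deposited value equals a whole count plus 0.5, divided by a library size, in M reads, that includes a scaling factor, as found by testing the table itself: with the lowest value of a library taken as a count of 0, 100% of values came back as whole counts within 0.02. Total counts ran from 11.58 to 22.47 M reads per library. In a library with a count of 0, a floor of 3 counts, with the 0.5 added, corresponds to a value between 0.145 and 0.32. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Standard deviations are between libraries.

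Genes with a value of at least 1 in at least 4 libraries were tested, 16985 in all, and 126 were not. A pseudocount of 1 was added before log2. One linear model over the 6 groups was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, and 13 contrasts were drawn from it: KO against WT at each day and as the mean of the 3 days, day 1 or 4 against day 0 and day 4 against day 1 within each genotype, and the 3 changes of the genotype difference between days. All tests were two-sided, p was adjusted by Benjamini-Hochberg within a contrast, and the threshold was 0.05. All p-values given are from limma unless another tool is named.

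A total of 40 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists, and again with a correlation estimated for each list. Beside each count of members past the threshold stands the count adjusted over the list alone where it differs or matters. Genes to be named were set by a rule written before the data were examined. It takes Lamp2, up to 12 genes in each direction with the largest changes in the genotype comparisons and the WT injury comparisons (passing the test, groups not overlapping, mean of at least 8, no predicted genes), the 10 strongest per interaction, up to 4 members per list and contrast, and 11 genes fixed by name, Lamp2 included. The text names a part of these. Values of genes with a total of 5 counts or fewer over the 4 libraries of a group compared were left out, a choice made after they were seen, because their fold changes rest on the pseudocount. Fold changes of other genes with low counts depend on it too, and 4 of those printed (Cd320, Slc15a2, Asns and Tnc) had a total of 12 to 15 counts in a group compared.

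Gene symbols came from the table, and 45 missing or date-like symbols were looked up by identifier, of which 23 had date form. Gene types, chromosomes and neighbours came from GENCODE M21 on GRCm38, which is another build than mm39, so no coordinates are given; 17089 of 17111 identifiers were found in the name table and 16963 of the 16985 tested had a type. Reads of near-identical copies, such as Eno1 with Eno1b and Plac9a with Plac9b, and of overlapping or antisense genes may be divided between them, so these values are uncertain.

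The model was tested on simulated counts for the genotype comparison at each day, over 16985 genes. At each day 16785 of them were unchanged, and 67, 67 and 66 were changed by 1.5-, 2- and 4-fold. The share of calls that were unchanged genes depends on these numbers, so it does not carry over to the real calls. At day 0, 78.7% of 357 calls were unchanged genes and 75.8% of 4-fold, 32.8% of 2-fold and 5.97% of 1.5-fold changes were found. At day 1, 5.36% of 56 calls were unchanged genes and 62.1% of 4-fold, 14.9% of 2-fold and 2.99% of 1.5-fold changes were found. At day 4, 25.6% of 82 calls were unchanged genes and 59.1% of 4-fold, 32.8% of 2-fold and 0 of 67 1.5-fold changes were found by limma (0 by edgeR and 1 by DESeq2). The list test was simulated for day 1 only, where a list moved by 1.5-fold was called (camera, adjusted p = 2.55e-23) and 0 of 40 random lists were. Simulated genes were drawn independently of each other, so this simulation cannot show false list calls that come from correlation between genes.

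Alternatives written before the data were examined were no filter, a stricter filter (at least 5 in at least 8 libraries), quantile normalization, no mean-variance trend, library weights, only the groups compared, the replicate number as a block, pseudocounts of 0.5 and 5, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, leaving out each library in turn, and for the lists an estimated correlation and fry. Alternatives chosen after seeing the data were no pseudocount, rescaling without mitochondrially encoded genes, and the means of days 0 and 1 and of days 1 and 4.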

Results

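Muscle stem cells, the Pax7-expressing cells that rebuild skeletal muscle after damage, were profiled by bulk RNA sequencing in 24 libraries from mouse muscle. The libraries fall into 6 groups of 4, made by 2 genotypes and 3 days. WT cells carried intact Lamp2a, and KO cells, labelled as the Lamp2a knockout, came from mice in which a Pax7-driven inducible Cre targeted Lamp2a, the splice form of Lamp2 that encodes the lysosomal receptor of chaperone-mediated autophagy. Muscles were uninjured (day 0) or taken 1 or 4 days after injection of 50 µL of 10 µM cardiotoxin, a snake venom toxin that kills myofibres. The design asks how muscle stem cells change after injury, and how KO cells differ from WT at each day. The sample titles name Pax7CreER for KO only, and no group is labelled as carrying Cre with intact Lamp2a. Effects of the Cre allele therefore cannot be told apart from those of Lamp2a loss in any genotype comparison. Total counts ranged from 11.58 to 22.47 M reads per library. The labels do not say whether the 4 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Values below are normalised read counts. A log2 fold change is on the log2(value + 1) scale, which understates the change of low genes. Its standard error (n = 4 libraries per group) comes from the model over all 24 libraries, so it does not show the spread of the groups compared alone.

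The libraries separated by day first. The first principal component held 32.4% of the variance and the second 26.3%. Correlations between libraries of one group were lowest at day 0 (0.852 to 0.883), higher in KO (0.884 to 0.908) and WT (0.951 to 0.956) at day 4, and highest at day 1 (0.968 to 0.985).

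**Figure D1:**
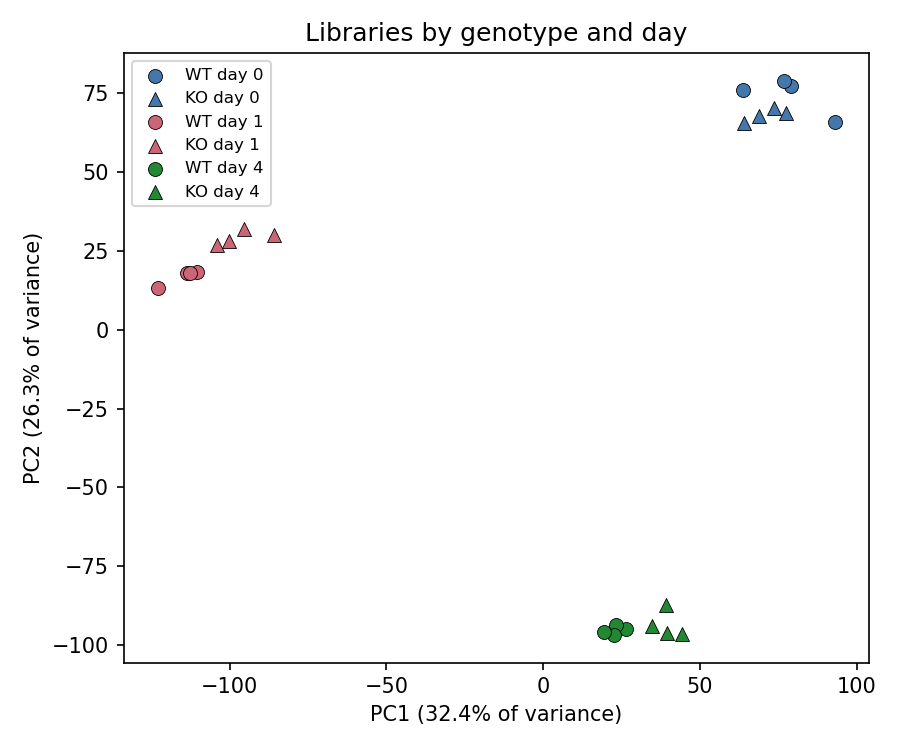
Principal components of log2(value + 1) over 16985 genes, with the first component (32.4% of the variance) on the x axis and the second (26.3%) on the y axis. Each point is 1 of 24 libraries, colour marks the day and the marker marks the genotype, and the 3 days form 3 separate clusters.

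The targeted gene was examined first, at the level of the whole gene, which sums all splice forms and so cannot show the loss of Lamp2a alone. Lamp2 (ENSMUSG00000016534) stood at 676 ± 151 (SD, n = 4) in WT and 582 ± 36.0 in KO at day 0, at 415 ± 35.0 and 390 ± 71.7 at day 1, and at 209 ± 13.1 and 222 ± 49.3 at day 4. The genotype differences of Lamp2 were −0.19 ± 0.16, −0.10 ± 0.16 and 0.06 ± 0.16 on the log2 scale at days 0, 1 and 4, and none passed the test (limma, adjusted p = 0.523, 0.887 and 0.981). Lamp2 fell by 1.67 ± 0.16 from day 0 to day 4 in WT and by 1.42 ± 0.16 in KO, but only by 0.574 and 0.418 under quantile normalization. These gene-level values check neither the genotype labels nor the splice form.

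After 1 day of injury, genes of DNA replication were higher in WT cells. Mcm2 and Mcm3, subunits of the replicative helicase, rose by 6.17 ± 0.44 and 6.07 ± 0.50, and Asns, which makes asparagine, by 6.21 ± 0.40. Tnc, an extracellular matrix glycoprotein, rose by 6.91 ± 0.46. Myod1, the transcription factor of myogenic commitment, rose by 3.28 ± 0.30 and Mki67, a proliferation marker, by 2.75 ± 0.69. Some sizes depended on the setting, with ranges over all settings of 4.209 to 8.708 for Asns and 4.909 to 9.277 for Tnc, which had 13 and 15 counts in all in WT at day 0, and of 1.355 to 4.928 for Mki67. The noncoding RNAs Neat1, Meg3 and Kcnq1ot1 fell by 4.58 ± 0.11, 4.57 ± 0.17 and 4.39 ± 0.12, and Calcr, a receptor that holds stem cells in quiescence, fell by 1.46 ± 0.37. Pax7 changed by 0.39 ± 0.23 and did not pass the test (limma, adjusted p = 0.158), but did without WT day 0 replicate 1 (0.65, adjusted p = 0.0111, in a range up to 0.428 over all settings).

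Of 30 DNA replication genes, 26 rose in WT at day 1 (26 adjusted over the list alone; median 3.22), and of 36 proteasome genes 33 rose, among them Psma7 by 1.91 ± 0.15, while the activator subunit Psme4 fell by 2.04 ± 0.15. Of 23 genes of the tricarboxylic acid cycle, 20 rose (21 adjusted over the list alone), led by Sdhc with 3.05 ± 0.22. Of 58 nuclear genes of oxidative phosphorylation, 46 rose (47 adjusted over the list alone), with Cyc1 at 3.22 ± 0.16, but the list's adjusted p was 0.0921 with an estimated correlation. All 13 mitochondrially encoded genes fell (median −1.69; adjusted p = 0.295 with an estimated correlation). Of 24 genes linked to quiescence, 13 fell and 2 rose (the same counts adjusted over the list alone; adjusted p = 0.0242 with an estimated correlation). Over all genes, 4707 were higher and 4221 lower in WT at day 1 (limma, adjusted p under 0.05), and camera called 15 of the 40 fixed lists, 7 of them with an estimated correlation. More genes were lower than higher with quantile normalization (4203 higher and 4720 lower), edgeR (3982 and 4416) and DESeq2 (4401 and 4738).

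At day 4, WT libraries carried macrophage transcripts that were low at day 0, together with genes of cell division and muscle differentiation. All 20 macrophage and monocyte markers rose (20 adjusted over the list alone; median 4.84), among them Lyz2, which encodes lysozyme, by 7.26 ± 0.84 (8.652 without WT day 0 replicate 4; 5.059 to 8.652 over all settings). Lyz2 averaged 746 ± 110 in WT and 611 ± 52.9 in KO at day 4. Of 30 mitosis genes, 28 rose (median 3.3; adjusted p = 0.0311 with an estimated correlation), including Mki67 by 5.31 ± 0.69 (3.511 to 7.631 over all settings). Of 32 differentiation and contractile genes, 26 rose (27 adjusted over the list alone; median 2.89), including Ttn, the giant sarcomeric spring protein, by 4.86 ± 0.38.

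Stress and quiescence genes fell in WT over the same 4 days. Of 30 cytosolic chaperones, 29 fell (29 adjusted over the list alone; median −2.13), with Hspa1b at −7.33 ± 0.27 and Hsp90aa1 at −3.23 ± 0.11, and of 27 immediate early genes 23 fell (median −2.12), such as Fosl2 at −2.15 ± 0.13. Of 24 quiescence genes, 17 fell, with Calcr at −5.15 ± 0.37, and Spry1, an inhibitor of growth factor signalling, fell by 2.61 ± 0.30. Chaperones and immediate early genes fell together, and stress from cell isolation in the day 0 samples was not tested as a source of these falls. Nor was the presence of other cells at day 4, when macrophage transcripts were high. Cytosolic ribosomal protein genes were lower in 76 of 78 cases (median −0.97), but adjusted p was 0.229 with an estimated correlation, and the direction of the list turned under quantile normalization (adjusted p = 0.261). In all, 4370 genes were higher and 3205 lower at day 4, and 17 lists were called, 9 with an estimated correlation. The excess of higher genes was lost with quantile normalization (3583 higher and 3877 lower) and edgeR (2976 and 2977), but not with DESeq2 (3785 and 2980). In the main model the median log2 fold change of all genes was 0.232 for this comparison, so falls are given against a slightly raised centre.

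Between days 1 and 4 in WT, 4719 genes rose and 3847 fell. More fell than rose with the stricter filter (2876 higher and 3629 lower), and quantile normalization gave 3654 and 3657. The excess of higher genes stayed with edgeR (4070 and 3268) and DESeq2 (4822 and 3394). The macrophage markers rose again (20 of 20, median 4.9), as did Col1a2, a fibrillar collagen chain, by 7.70 ± 0.38, and Pthlh, which encodes parathyroid hormone-related protein, by 5.67 ± 0.27. Ribosome biogenesis genes fell in 29 of 32 cases (30 adjusted over the list alone; median −1.87), with Ncl, which encodes nucleolin, at −2.34 ± 0.09, and proteasome genes fell in 35 of 36 (median −1.78). Myod1 fell by 4.65 ± 0.30, Cd34, a surface marker of quiescent cells, by 5.03 ± 0.27, and Chodl by 6.06 ± 0.24. All 13 mitochondrially encoded genes rose (median 3.02; adjusted p = 0.0833 with an estimated correlation).

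KO cells went through much of the same response. At day 1, 4108 genes rose and 3644 fell (53% higher), but more fell than rose with DESeq2 (3527 higher and 4665 lower), edgeR (3445 and 3874) and quantile normalization (3514 and 3866). In limma, 3054 of those that rose had also risen in WT (1140 for independent lists), while 2587 fell in both (906 for independent lists). Fold changes correlated across genes between the genotypes with r = 0.755 at day 1, 0.76 at day 4 and 0.851 between days 1 and 4, although genes are not independent replicates. In KO at day 1, 25 of 30 chaperones rose (median 1.38; adjusted p = 0.003 with an estimated correlation), such as Hspd1 by 2.31 ± 0.14, and 19 of 24 NRF2 and oxidative stress genes rose (20 adjusted over the list alone; median 1.84). Hmox1, the haem-degrading enzyme induced by oxidative stress, rose by 3.60 ± 0.18 in KO. Pax7 fell by 1.20 ± 0.23 and Myod1 rose by 4.21 ± 0.30. At day 4, 3794 genes were higher and 3084 lower than at day 0 in KO, with 18 of 20 macrophage markers higher (19 adjusted over the list alone; median 4.3) and 17 of 24 quiescence genes lower, among them Calcr at −7.16 ± 0.37. For this comparison more genes were lower than higher with quantile normalization (3362 higher and 3411 lower) and edgeR (2614 and 2758), but not with DESeq2 (3469 and 2757). Between days 1 and 4 in KO, 4453 genes rose and 3974 fell, and all 58 nuclear genes of oxidative phosphorylation fell (median −1.46; adjusted p = 0.0198 with an estimated correlation). Over all genes, more fell than rose with the stricter filter (2564 higher and 3778 lower) and quantile normalization (3503 and 3604), but not with edgeR (4136 and 3478) or DESeq2 (5298 and 3257).

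In uninjured muscle, chaperone and ribosome biogenesis genes were lower in KO cells than in WT, and single genes differed in both directions. Pthlh stood at 580 ± 77.9 in KO and 0.712 ± 0.440 in WT, a log2 difference of 8.43 ± 0.27 (limma, adjusted p = 1.58e-16), with all 4 KO libraries above all 4 WT libraries. Flrt1, a cell adhesion receptor, was higher by 4.68 ± 0.41, Sparc, a matrix glycoprotein, by 2.18 ± 0.18, Col3a1 by 1.55 ± 0.23 and the cell cycle inhibitor Cdkn1a by 0.89 ± 0.11. Sparc and Col3a1 belong to the extracellular matrix list, of which 8 of 34 genes were higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), and Col3a1 also to the markers of fibro-adipogenic progenitors, of which 4 of 17 were higher (5 adjusted over the list alone; median 0.61; adjusted p = 0.301 with an estimated correlation). The mean log2 value of these markers overlapped between the genotypes, with 4.28 to 4.916 in KO libraries and 3.686 to 4.548 in WT, as did that of smooth muscle and pericyte markers, with 3.545 to 3.658 and 2.749 to 3.596. Mature myofibre markers did not overlap, with 2.267 to 2.587 in KO and 1.66 to 1.906 in WT, although only 3 of 16 were called higher and 1 lower (3 and 2 adjusted over the list alone) and the list was not called (adjusted p = 0.0683). Of 32 differentiation and contractile genes, 8 were higher (9 higher and 1 lower adjusted over the list alone; median 0.59; adjusted p = 0.000809, but 0.211 with an estimated correlation). A difference in other cells or fibre fragments in the libraries is not excluded. Ptgds, a prostaglandin synthase, was lower in KO (−3.43 ± 0.44), as were Cd320, a vitamin B12 uptake receptor (−3.27 ± 0.30), and Hmox1 (−2.12 ± 0.18). The size of some of these changes depended on the pseudocount and tool, and ranged over all settings from 6.672 to 9.831 for Pthlh, from 3.191 to 5.969 for Flrt1 and from −6.424 to −1.605 for Cd320, which had 14 counts in all in KO. Myf5, a myogenic factor, differed by −1.41 ± 0.19 (adjusted p = 4.36e-05, but 0.0518 with the 8 day 0 libraries alone, in a range of 1.34e-10 to 0.0518 over all settings), while Pax7 differed by 0.21 ± 0.23 and did not pass the test.

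Of 30 cytosolic chaperones, 23 were lower in KO at day 0 (25 adjusted over the list alone; median −0.84; camera adjusted p = 3.59e-19). They included Hsph1 (−1.50 ± 0.17), Hspe1 (−1.51 ± 0.14), Dnaja1 (−1.05 ± 0.11) and Hsp90ab1 (−0.72 ± 0.06). Of 32 ribosome biogenesis genes, 12 were lower (21 adjusted over the list alone; median −0.68), including Gnl3 (−0.97 ± 0.12) and Ncl (−0.80 ± 0.09). Those 2 lists kept their call with an estimated correlation (adjusted p = 0.000359 and 0.00044), and the other 12 of the 14 called lists did not. Among the latter, 6 of 30 mitosis genes were higher (11 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation) and 14 of 58 nuclear oxidative phosphorylation genes were higher (19 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). The mitosis gene Mki67 was 43.4 in KO replicate 1. It was 0.304 to 3.24 in the other KO libraries and 0.0997 to 2.23 in WT. How far that library carried the mitosis list was not tested.

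Across all genes, 819 were higher and 837 lower in KO at day 0 with the spread shared by all 24 libraries. The count fell to 68 genes (34 higher and 34 lower) with the 8 day 0 libraries alone, and to 309 with library weights. On simulated data for this comparison, 281 of 16785 unchanged genes were called, which made up 78.7% of the 357 calls. That share rests on how few genes were changed in the simulation and does not carry over to the real count. A fit of the simulated day 0 libraries alone had 11 calls in all, called 0 unchanged genes and found 16.7% of 4-fold changes.

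At day 1, KO libraries carried more stress response transcripts than WT and fewer transcripts of mature myofibre markers. Hmox1 reached 1585 ± 177 in KO and 45.4 ± 4.75 in WT, a log2 difference of 5.09 ± 0.18 (limma, adjusted p = 4.02e-16), with all 4 KO libraries above all 4 WT libraries. Pthlh was higher by 8.03 ± 0.27, Gdf15, a stress-induced cytokine, by 4.65 ± 0.26 and Cyp26a1, which degrades retinoic acid, by 5.94 ± 0.68. Eno1b, a retrocopy of the enolase gene Eno1 whose reads may be divided between both copies, was higher by 6.57 ± 0.23. Lower in KO were Pax7 (−1.39 ± 0.23), with 32.0 ± 3.70 against 85.3 ± 10.1 in WT, Myf5 (−0.88 ± 0.19), Chodl (−2.39 ± 0.24) and Nppc, a natriuretic peptide precursor (−2.75 ± 0.35). Whether the Pax7-driven Cre of KO mice alters Pax7 reads was not tested. The Pax7 difference did not pass at day 0 or day 4. Calcr differed by −1.41 ± 0.37 (adjusted p = 0.0137, but up to 0.0908, without a pseudocount, in a range from 0.000478 over all settings), and Myod1 by 0.92 ± 0.30, which did not pass the test (adjusted p = 0.0573) but did with the 8 day 1 libraries alone (0.00554, in a range of 0.000189 to 0.555 over all settings).

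Of 24 NRF2 and oxidative stress genes, 13 were higher in KO at day 1 (15 adjusted over the list alone; median 0.78), including the ferritin chains Ftl1 (1.91 ± 0.10) and Fth1 (1.03 ± 0.10). Of 30 chaperones, 15 were higher (20 adjusted over the list alone; median 0.53; camera adjusted p = 9.45e-14), such as Cryab (3.10 ± 0.23), Hspa1b (2.64 ± 0.27) and Hsph1 (1.66 ± 0.17). The constitutive chaperone Hspa8, which delivers substrates to LAMP2A, was higher by 0.80 ± 0.12, but its direction turned under quantile normalization (−0.12), where it was not called. The list of chaperone-mediated autophagy components and modulators had 6 of 23 members higher (13 adjusted over the list alone; median 0.57), and 5 of its genes belong to the chaperone list as well. Of 39 macroautophagy genes, 13 were higher (14 adjusted over the list alone; median 0.21), including the cargo receptor gene Sqstm1 (1.65 ± 0.14) and Gabarapl1 (1.86 ± 0.22). These lists kept their call with an estimated correlation (adjusted p = 0.000384, 0.000955, 0.00166 and 0.0268), but the chaperone-mediated autophagy list lost its call under quantile normalization (adjusted p = 0.172).

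Mature myofibre markers were lower in KO at day 1 in 12 of 16 cases (12 adjusted over the list alone; median −2.08; adjusted p = 0.000384 with an estimated correlation), including Acta1, the skeletal actin gene (−3.12 ± 0.56), and Tnni2, a fast troponin (−2.51 ± 0.47). A difference in fibre fragments in the libraries is not excluded at this day either. Of 20 p53 targets, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0116 with an estimated correlation), with Fas at 1.90 ± 0.26 and Cdkn1a at 0.84 ± 0.11. In the interferon response list, 5 of 30 were lower and 3 higher (6 and 3 adjusted over the list alone; median −0.74; adjusted p = 0.0268 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 60 of 78 cases (72 adjusted over the list alone; median 0.61), among them Rpl13 (0.90 ± 0.10), but their adjusted p was 0.177 with an estimated correlation. Of 13 mitochondrially encoded genes, 11 were higher (median 1.13; adjusted p = 0.132 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 11 of 58 higher (16 adjusted over the list alone), a list whose direction turned under quantile normalization (adjusted p = 0.956) and whose adjusted p was 0.425 with an estimated correlation.

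In all, 1209 genes were higher and 353 lower in KO at day 1 (77.4% higher), and 19 lists were called, 7 with an estimated correlation. The day 1 libraries alone called 3958 genes, 2169 higher and 1789 lower, library weights called 4920 with 56.1% higher, quantile normalization called 996, and DESeq2 put 64.4% of its calls on the higher side. Fewer genes were detected in KO than in WT at this day, 14982 ± 91.4 against 15802 ± 68.6 per library.

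**Figure D2:**
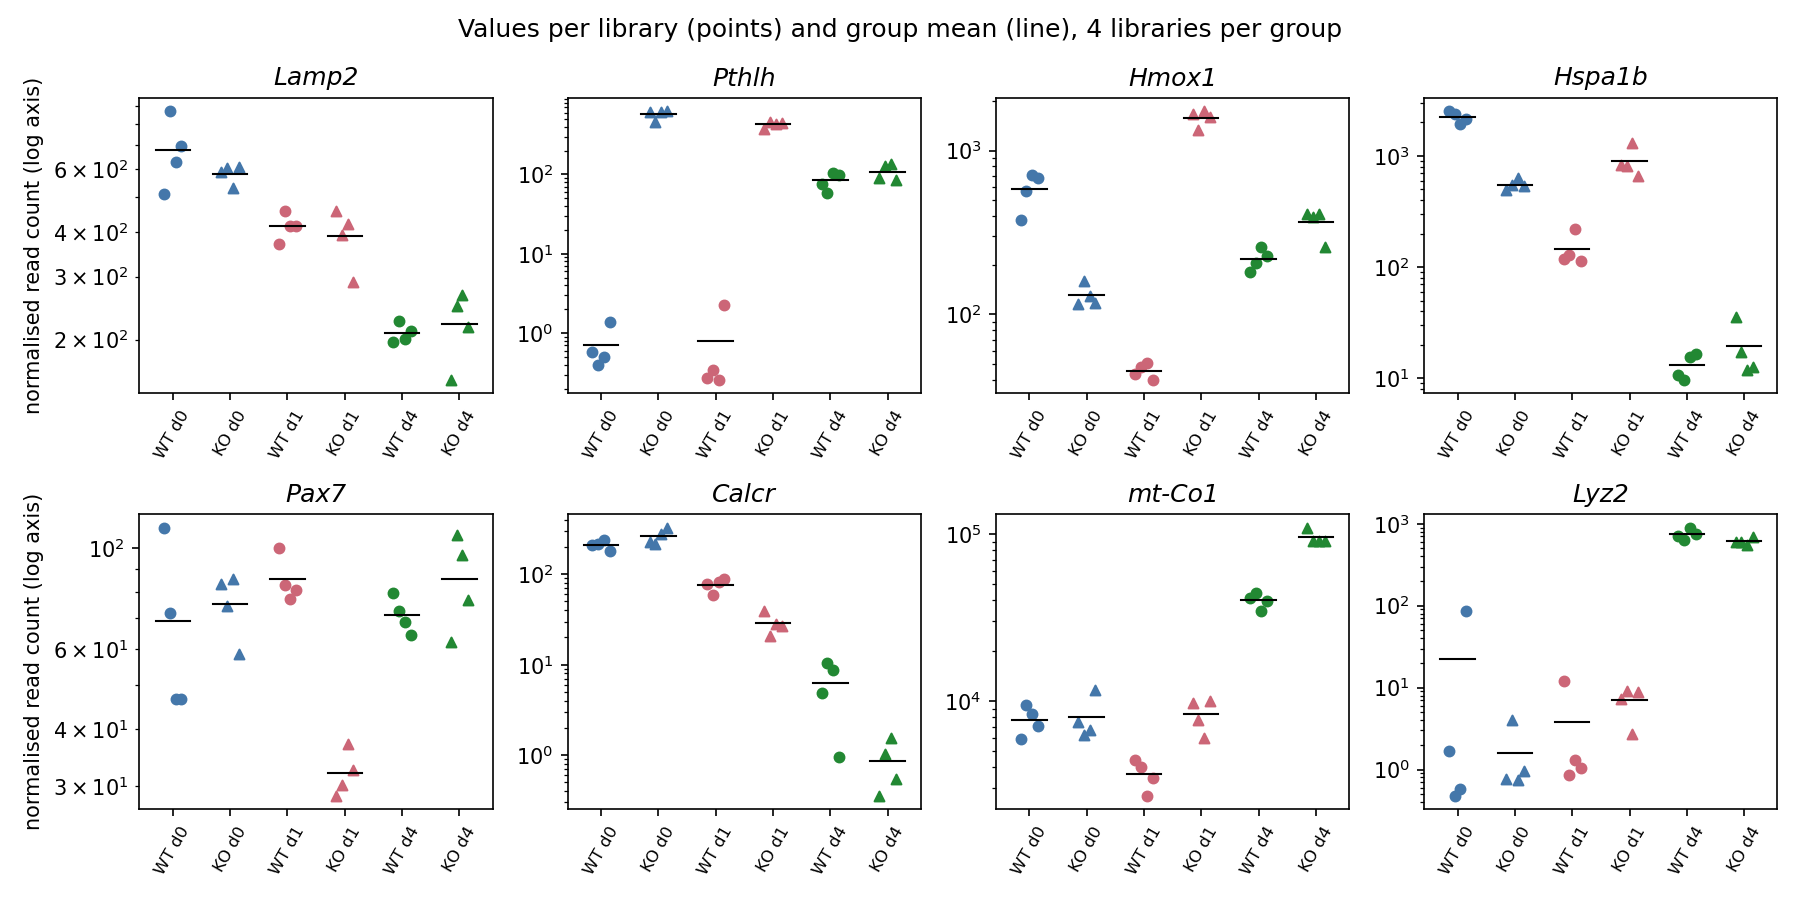
Normalised read count (log axis) of 8 genes in each of the 24 libraries, with points for libraries and a line at each group mean. Pthlh lies near 0.712 in WT and 580 in KO at day 0, and Hmox1 near 45.4 in WT and 1585 in KO at day 1, whereas Lamp2 overlaps between the genotypes at each day.

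At day 4, 179 genes differed by genotype with the spread shared by all 24 libraries, and 128 with the 8 day 4 libraries alone. Mitochondrially encoded transcripts were higher in KO, with 11 of 13 genes called (13 adjusted over the list alone; median 1.08; camera adjusted p = 7.91e-25), such as mt-Co1 (1.25 ± 0.18) and mt-Atp6 (1.17 ± 0.17). All mitochondrial genes, with mt-Rnr1 and mt-Rnr2 beside the 13 listed, took 44.5 ± 2.28% of all counts in KO and 29.9 ± 1.58% in WT (n = 4 each). Fewer genes were detected in KO here as well, 15508 to 16174 per library against 16414 to 16547 in WT. Under quantile normalization mt-Co1 and mt-Atp6 lost their calls (0.14, adjusted p = 0.902, in a range from 1.43e-07 over all settings, and 0.03, adjusted p = 0.995, in a range from 2.52e-07), and so did the list (adjusted p = 0.369), which had adjusted p = 0.0655 with an estimated correlation. Eno1b was higher in KO (4.36 ± 0.23) and Eno1 lower (−1.41 ± 0.15), and the copies Plac9a and Plac9b were higher by 3.69 ± 0.42 (2.134 to 6.483 over all settings) and 3.36 ± 0.21. Both pairs may share reads. Mid1, a ubiquitin ligase, was higher by 2.01 ± 0.28. Slc15a2, a peptide transporter, was lower (−3.68 ± 0.32, but −6.154 to −1.945 over all settings, with 12 counts in all in KO), as were Asns (−3.09 ± 0.40), Erfe, the hormone erythroferrone (−2.32 ± 0.27), and the small heat shock protein gene Hspb1 (−1.24 ± 0.20).

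Differentiation and contractile genes had a median of −0.56 at day 4, with 1 of 32 called lower (2 adjusted over the list alone), and mitosis genes a median of −0.77 with 1 of 30 called lower. Nuclear oxidative phosphorylation genes had a median of −0.21 with 3 of 58 lower (4 adjusted over the list alone). These lists had adjusted p = 0.0655, 0.124 and 0.329 with an estimated correlation, and none of the 16 lists called at day 4 kept its call that way. Calcr differed by −1.72 ± 0.37 (adjusted p = 0.0159, but 2.17e-07 to 0.238 over all settings, the highest with the 8 day 4 libraries alone), Pax7 by 0.23 ± 0.23, Myog by −0.43 ± 0.96 and Cdkn1a by −0.29 ± 0.11, of which only Calcr passed. Of 20 macrophage markers 1 was lower (2 adjusted over the list alone; median −0.24), so both genotypes carried these transcripts at day 4. Over all genes, 90 were higher and 89 lower. The count was 101 with a stricter filter, 85 with edgeR (70.6% of them higher, against 50.3%), and 117 without WT day 4 replicate 1. DESeq2 put 63.5% of its calls on the higher side.

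**Figure D3:**
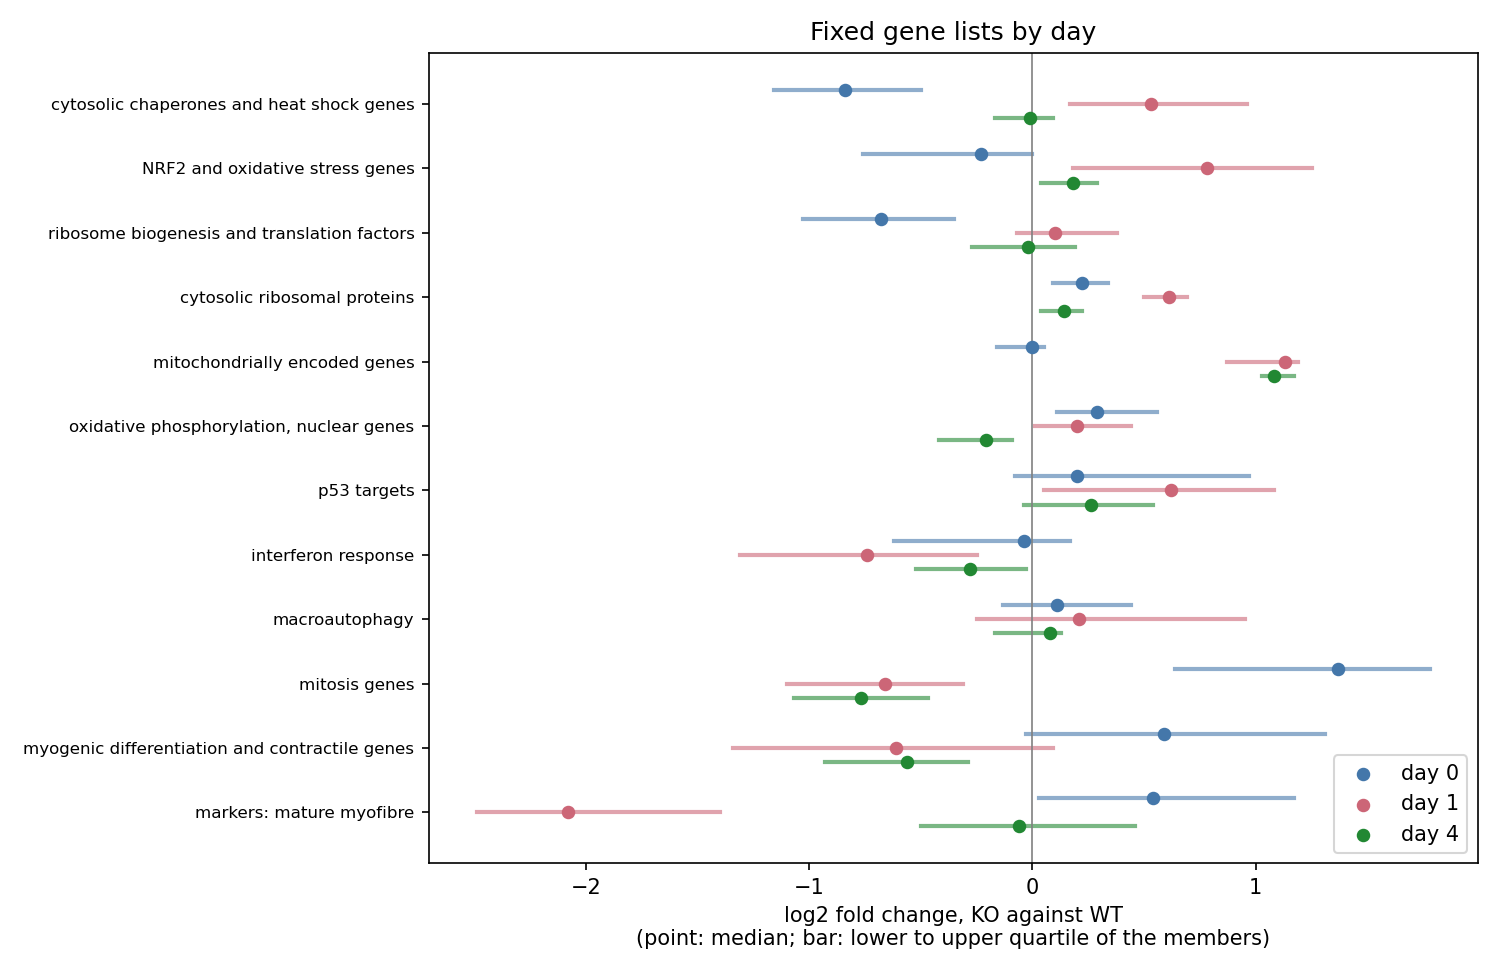
Median log2 fold change (KO against WT) of 12 fixed gene lists at days 0, 1 and 4, on the x axis, with 1 row per list and horizontal bars from the lower to the upper quartile of the members. The chaperone list sits at −0.84 at day 0 and 0.53 at day 1, and the mitochondrially encoded list at 1.13 at day 1 and 1.08 at day 4.

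Averaged over the 3 days, 583 genes were higher and 278 lower in KO. Pthlh (5.61 ± 0.16), Eno1b (4.78 ± 0.13), Flrt1 (3.17 ± 0.24), Cap1 (2.74 ± 0.27) and Gdf15 (2.19 ± 0.15) were among the genes that were higher. Of 20 p53 targets, 6 were higher (8 adjusted over the list alone; median 0.45; adjusted p = 0.00591 with an estimated correlation). The p53 target, NRF2 and interferon lists kept their call with an estimated correlation among the 17 lists called. Only 9 genes were called higher at each of the 3 days (0.309 for independent lists) and 1 lower (0.0912 for independent lists). The 9 were Cap1, Eno1b, Gm10036, Gm10282, Gm12191, Gm17711, Gm7125, Ndufs5-ps and Eif3s6-ps2, the 1 was Ptgds, and those outside the rule for named genes were named after their values were seen. The day 4 call of Cap1 was lost with edgeR (adjusted p = 0.106, in a range of 0.000402 to 0.114 over all settings). DESeq2 called 1397 genes for this mean.

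The genotype differences themselves changed with injury. From day 0 to day 1, the KO minus WT difference changed in 1966 genes, 1270 upward and 696 downward, by the interaction test. Hmox1 shifted by 7.21 ± 0.26, Txnip, a redox regulator, by 3.87 ± 0.25, Hsph1 by 3.16 ± 0.24 and Ftl1 by 2.17 ± 0.15, while Pax7 shifted by −1.59 ± 0.32. The chaperone list shifted upward in 25 of 30 members (27 adjusted over the list alone; median 1.43; adjusted p = 5.01e-05 with an estimated correlation), and 163 genes were lower in KO at day 0 and higher at day 1 (59.6 for independent lists), while 28 were higher and then lower (17 for independent lists). The same direction at both days was seen in 94 genes that were higher (58.3 for independent lists) and 26 that were lower (17.4 for independent lists). Mature myofibre markers shifted downward in 9 of 16 (12 adjusted over the list alone; median −2.17). DESeq2 put 50.0% of its calls upward, against 64.6%.

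From day 0 to day 4 the genotype difference changed in 678 genes, 342 upward and 336 downward. Pthlh shifted by −8.05 ± 0.39, since WT cells at day 4 had 84.0 ± 20.4 and KO cells 109 ± 25.6. Sparc shifted by −2.33 ± 0.25, Cdkn1a by −1.18 ± 0.15, Mid1 by 3.68 ± 0.39 and Hsp90ab1 by 0.85 ± 0.09. This count was 227 with library weights, 234 with only the libraries of these 2 days and 1366 with DESeq2. Between days 1 and 4 it changed in 675 genes, 129 upward and 546 downward, with Pthlh at −7.66 ± 0.39, Hmox1 at −4.35 ± 0.26, Gdf15 at −4.43 ± 0.37 and Plac9b at 4.11 ± 0.30, and Pax7 at 1.62 ± 0.32. Library weights called 1682 genes there and the libraries of these 2 days alone 1523, and DESeq2 put 40.2% upward, against 19.1%.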

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

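The tests on immediate early genes, on quantile normalization of the chaperone list, on the unscaled mitochondrial share at both days and on nuclear retained RNAs at day 1 were chosen only after the results were seen.

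Each library measure and each named gene was compared among the 4 libraries of a group, in 231 group comparisons in all, and a library was singled out when its gap to the nearest of the others took most of the range (Dixon's ratio above its 95% critical value). Of 30 comparisons of library measures, 3 did so, and of 201 comparisons of genes, 15 (7.46%), whereas chance gives about 1 in 20. KO day 4 replicate 2 had a total of 14.05 M counts against 17.11 to 17.38 M in the others. KO day 0 replicate 3 had 14963 detected genes against 14547 to 14615. KO day 4 replicate 1 had 47.89% of counts on mitochondrial genes, mt-Rnr1 and mt-Rnr2 included, against 43.17 to 43.45%.

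Among the genes, Pthlh was 464 in KO day 0 replicate 2 against 614 to 623, and 2.29 in WT day 1 replicate 4 against 0.258 to 0.344. In KO day 0 replicate 2, Sparc was 1460 against 1890 to 1920 and Col3a1 703 against 789 to 808. At day 0 in WT, Hsp90ab1 was 4510 in replicate 3 against 4130 to 4140, Mid1 was 95.4 in replicate 3 against 188 to 214, Ttn was 18.7 in replicate 3 against 26.8 to 27.7, Gnl3 was 952 in replicate 4 against 770 to 794, and Lyz2 was 86.5 in replicate 4 against 0.474 to 1.69. Hsph1 was 712 in KO day 1 replicate 2 against 840 to 845. At day 4, Cdkn1a was 306 in WT replicate 2 against 364 to 374, Plac9b was 2.4 in WT replicate 2 against 5.89 to 6.18, Hmox1 was 259 in KO replicate 4 against 396 to 411, mt-Co1 was 109000 in KO replicate 1 against 90600 to 90900, and Hspb1 was 28.7 in KO replicate 2 against 21 to 22.1.

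The genotype difference itself changed between days in 1966 genes from day 0 to day 1, 678 from day 0 to day 4 and 675 from day 1 to day 4, by the interaction test in limma. From day 0 to day 1 it changed by 7.21 for Hmox1, 3.87 for Txnip, 3.16 for Hsph1, 2.17 for Ftl1 and −1.59 for Pax7. From day 0 to day 4 it changed by −8.05 for Pthlh, 3.68 for Mid1, −2.33 for Sparc, −1.18 for Cdkn1a and 0.85 for Hsp90ab1. From day 1 to day 4 it changed by −7.66 for Pthlh, −4.43 for Gdf15, −4.35 for Hmox1, 4.11 for Plac9b and 1.62 for Pax7.

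Chance in forming the groups was tested by fitting other splits of the same libraries, the real one included in each count. For the interaction from day 0 to day 1, 1 of 100 splits gave as many genes as the real 1966, and the highest other gave 1148. For day 0 to day 4, 1 of 100 gave as many as 678, and the highest other gave 334. For day 1 to day 4, 2 of 100 gave as many as 675. The other of those 2 gave 1024 genes, and it exchanged the genotypes of all 4 libraries at day 4 and of none at day 1, so it measures the sum of both genotype differences, a structure of the samples. In the genotype comparisons, 1 of 35 splits gave as many genes as the real 1656 at day 0 (highest other 491), 1562 at day 1 (highest other 9) and 179 at day 4 (highest other 11), and 1 of 100 as many as 861 for the mean (highest other 202). In the injury comparisons, 1 of 35 splits gave as many genes as the real one: WT day 1 with 8928 (highest other 3), WT day 4 with 7575 (20), KO day 1 with 7752 (6), KO day 4 with 6878 (263), day 4 against day 1 in WT with 8566 (0) and in KO with 8427 (7). The share was under 0.05 in each of these 13 comparisons, which argues against a chance assignment of libraries to groups. A count of 1 is the lowest possible, since the real split is included. If the libraries of a group came from 1 animal or preparation, the splits cannot exclude a difference between animals or preparations.

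Chaperones were lower in KO at day 0 and higher at day 1. Stress from cell isolation that moves chaperones and immediate early genes alike was tested on the latter. The genotype difference of immediate early genes changed by a median of −0.7 from day 0 to day 1, with 4 genes up and 12 down past the threshold. The scaling between libraries was tested by quantile normalization, after which the chaperone list still passed at day 0 (median −0.71 against −0.84 before; adjusted p = 1.37e-14) and at day 1 (median 0.17 against 0.53 before; adjusted p = 0.0036), although the day 1 difference was smaller and its member Hspa8 turned to −0.12. The tests argue against isolation stress that moves both lists alike, unless injury itself also moved the genotype difference of immediate early genes. They argue against scaling as the whole cause, and scaling may still set part of the size at day 1. A response of KO cells that starts below WT and rises above it after injury may explain the pattern, as a hypothesis found on these data and not itself tested. A difference in the time or handling of the samples that spares immediate early genes stays open.

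Mitochondrially encoded transcripts were higher in KO at days 1 and 4. The unscaled share of counts on all mitochondrial genes, mt-Rnr1 and mt-Rnr2 included, was already higher in KO. The log2 ratio was 0.78 at day 1 and 0.57 at day 4, so scaling between libraries cannot make the difference in this wider set alone. The share of the listed genes by themselves was not computed. Quantile normalization ended the day 4 call of the list (adjusted p = 0.369), with a median of 1.08 (quartiles 1.03 to 1.17) before and 0.05 (0 to 0.17) after. At day 4 all 13 genes were among the 100 highest values of each library, with a median rank of 12 in both genotypes, and that setting gives equal ranks equal values, so it has little room to show a difference there. Loss of cytoplasmic RNA from damaged KO cells would have raised nuclear retained RNAs alike. At day 4, 9 such RNAs had a median of 0.29 (quartiles −0.17 to 0.35), under 0.54, which is 0.5 times the median of the mitochondrial genes. That met the written criterion against this loss. However, Malat1 (0.68 ± 0.13) passed the test, and Meg3 (0.645 ± 0.172) also lay above 0.54 without passing (limma, adjusted p = 0.0779). Kcnq1ot1 (0.345 ± 0.122) and Neat1 (0.294 ± 0.112) were above 0 too. The RNAs below 0 (Mirg, Snhg11, Snhg14 and Ftx) had standard errors of 0.234 to 0.503. Since the RNAs with the smallest standard errors were all higher in KO, this loss stays open at day 4. At day 1 the same RNAs had a median of 0.36 (quartiles 0.19 to 0.83), with 3 called higher. The upper quartile lay above 0.56, the matching bound, so loss of cytoplasmic RNA stays open at day 1 as well. More mitochondrial RNA per KO cell is a candidate explanation that was not tested, since RNA per cell was not measured. A different mix of cells in the KO libraries stays open. Both genotypes held macrophage transcripts at day 4, and KO day 4 replicate 3 stood apart in the mean log2 value of fibro-adipogenic markers (6.011 against 4.224 to 4.743 in the other KO libraries) and of glial and Schwann cell markers (4.488 against 2.025 to 2.79). Without that library mt-Co1 (by 1.276) and mt-Atp6 were still called higher in KO at day 4.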

How the results depend on the processing

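Chosen only after the data were seen were no pseudocount, rescaling without mitochondrially encoded genes and the means of 2 days. Counts of genes that moved by over 1.5 times were these. At day 0 the genotype count of 1656 became 309 with library weights, 68 with only the groups compared and 2536 with DESeq2. At day 1 the 1562 became 996 with quantile normalization, 4920 with library weights and 3958 with only the groups compared. At day 4 the 179 became 101 with the stricter filter and 85 with edgeR. The mean of the 3 days went from 861 to 1397 with DESeq2. The interaction from day 0 to day 4 went from 678 to 227 with library weights, 234 with only the groups compared and 1366 with DESeq2, and that from day 1 to day 4 went from 675 to 1682 with library weights and 1523 with only the groups compared. The cause was not tested.

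Leaving out each library in turn gave 1561 to 1794 genes for the genotype at day 0, 1125 to 1337 at day 1, 117 (without WT day 4 replicate 1) to 204 at day 4 and 687 to 1000 for the mean. It gave 8194 to 8753 in WT at day 1, 6720 to 7406 in WT at day 4, 6950 to 7570 in KO at day 1, 6259 to 6646 in KO at day 4, 7670 to 7831 from day 1 to day 4 in WT and 7602 to 8019 in KO. The interactions gave 1556 to 2134, 473 to 892 and 503 to 654. Lamp2 ranged from −0.32 to −0.06, −0.19 to 0.03 and −0.04 to 0.22 between genotypes at days 0, 1 and 4.

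Of 110 named gene values, 107 kept their direction and call under quantile normalization and with only the groups compared, and 108 to 110 under each other setting run on all 110. DESeq2 gave a value for 106 and kept 106, the means of 2 days were run on 5 values each and kept 5, and leaving out 1 library kept 1072 of 1080. Hspa8 turned at day 1 under quantile normalization (−0.12). Myod1 at day 1 passed with the stricter filter, library weights, only the groups compared, a pseudocount of 5 and the replicate block (adjusted p = 0.0424). Calcr lost its day 1 call without KO day 1 replicate 2 (adjusted p = 0.0547) and its day 4 call without WT replicate 2 (0.0863), WT replicate 3 (0.0791) or KO replicate 1 (0.0542), and Cap1 its day 4 call without WT replicate 2 (0.0673), WT replicate 3 (0.0531) or KO replicate 3 (0.0508). Pax7 rose past the threshold in WT at day 1 without WT day 0 replicate 1.

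Lamp2 turned between days 1 and 4 under quantile normalization, to 0.01 in WT (adjusted p = 0.97) and 0.46 in KO (adjusted p = 0.0161). That setting moved the median of all genes by −0.138 in WT at day 1, −0.411 in WT and −0.302 in KO at day 4, and −0.239 and −0.264 between days 1 and 4 in WT and KO. DESeq2 moved it by −0.212 in KO at day 1, 0.292 between days 1 and 4 in KO, and −0.147 and 0.167 in the interactions to day 1 and from day 1 to day 4. Every other shift with quantile normalization, library weights, edgeR, DESeq2 or rescaling without mitochondrial genes was at most 0.134 in size. With library weights 56.1% of day 1 genotype calls were higher, against 77.4%, and with edgeR 70.6% at day 4, against 50.3%.

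With an estimated correlation, the called lists numbered 2, 7, 0 and 3 for the genotype at days 0, 1 and 4 and the mean, 7 and 9 in WT at days 1 and 4, 5 in KO at day 4, 15 from day 1 to day 4 in KO, and 7, 4 and 5 for the interactions. Fry called 28 and 37 in WT at days 1 and 4, and 33 and 32 in KO, but it does not compare a list with other genes. Under quantile normalization lists turned direction: at day 1 by genotype, oxidative phosphorylation (adjusted p = 0.956) and proteasome (0.167); in the mean, actin cytoskeleton (0.876); in WT at day 4, ribosomal proteins (0.261); in KO at day 4, oxidative phosphorylation (0.000617); from day 1 to day 4 in WT, actin cytoskeleton (0.954); and in the interaction to day 1, proteasome (0.821), actin cytoskeleton (0.599) and ribosomal proteins (0.699). The cause was not tested.

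The replicate numbers share only a number. Same-number correlations ran from −0.026 to 0.27, 0 of 15 group pairs had all above 0.1, and not every library correlated best with its own number. With the replicate block, counts changed little, from 1656 to 1637 at day 0, 1562 to 1537 at day 1 and 179 to 175 at day 4 for the genotype. Values at the floor cannot show differences at this depth.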

Other observations

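The tests on pseudogenes at day 0 and on the chromosomes that hold the genes were chosen only after the results were seen, as was the band between a clear yes and a clear no in the first pseudogene test.

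The 9 genes called higher in KO at each of the 3 days included 5 pseudogenes, whereas 671 of the tested genes (3.96%) were pseudogenes, by the types of GENCODE M21 on GRCm38. Eno1b took 1.55, 0.516 and 0.847% of the summed Eno1 and Eno1b values in WT at days 0, 1 and 4, and 29.9, 37.8 and 35.9% in KO. Their sum went from 266.8 in WT to 176.9 in KO at day 0, from 1734 to 2465 at day 1 and from 521.8 to 304.2 at day 4, so a move of reads between the copies with a constant sum does not account for the gain at day 1, whereas a division of a sum that itself changed stays open. Reads divided between near-identical copies by a difference in sequence between the genotypes would repeat at every day. Across 671 pseudogenes, genotype differences at days 1 and 4 correlated with r = 0.174, against −0.006 to 0.196 in 200 draws of other genes, of which 1 was as high, so the written criterion of exceeding every draw was missed. A value within the range of the draws was the written criterion against this explanation, but with only 1 draw as high the value lay at the edge of that range, so neither criterion decides on this explanation. The same r was 0.309 between days 0 and 1 (draws −0.207 to 0.067) and 0.164 between days 0 and 4 (draws −0.113 to 0.083), above every draw in both. The differences of pseudogenes thus repeated more than those of the drawn genes between day 0 and each later day, but not clearly between days 1 and 4. The 671 include the 5 pseudogenes called at all 3 days that prompted the test, so r partly restates that choice. What makes the differences repeat stays open, since other differences in sequence would do so too. Genes are not independent replicates.

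Variants carried along from another strain with the targeted locus, or with the Cre allele of KO mice, may also give differences that repeat at each day. Among 356 genes higher and 189 lower on average with 1 direction at all 3 days, a wider set than the 9, there were 22 adjacent pairs, against a median of 9 and a range of 1 to 21 in 1000 random draws. This met the written criterion for the explanation, but the count covers all chromosomes and does not test linkage to either locus. The pairs lay on 14 chromosomes with at most 4 on 1 chromosome, 3 of them were mitochondrial, and neighbouring genes share regulation. No conclusion on such variants is drawn from the count. The 9 genes lay on 7 chromosomes, so no single stretch holds all of them. Where the source genes of the copies among them lie was not examined. A stretch that holds such source genes, and so alters how reads are divided, was therefore not tested.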
